A study of Mus musculus with 96 samples.

How the data were processed

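Single nuclei and bulk samples of the mouse line KPC1199EGFP were measured by whole-genome sequencing after amplification with the SeqXE kit and ligation of adapters, per the labels' protocols. Bowtie 1.0 and the genome build mm9 are named in the submitters' processing notes. The construction of bins, any GC correction, the handling of duplicates and the segmentation method are not given in the sources used here. The deposited values are linear ratios to the library's own genome-wide level: the mean over bins of each library was close to 1, and values were equal over long runs of bins, as segment means are. They are not counts, so no depth, counting noise or bin noise could be had from them, and errors come only from the spread of nuclei. A ratio is relative within a nucleus, so a doubling of the whole genome that leaves no odd copy number cannot be seen from it. Smoothing by segments also hides any change shorter than the shortest segment the submitters' method allowed.

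The table was split at white space into 99 fields per line and sorted by position. It has 4906 bins, and chromosome codes after 19 were read as X, with 267 bins, and Y, with 3 bins. Positions are given in mm9, counted from 1, and each bin ends where the next begins. The gene table given for this work is of assembly GRCm38.p6, so none of its coordinates were used and no gene was placed in a bin. Not every gene of the lists is reported here. Each library was assigned to its gate by its title.

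The design assumed counts. Depth per nucleus, bin noise, the minimum totals, thinning to 1 depth and re-segmentation of each nucleus could not be done on ratios. All 94 nuclei were used, and the submitters' segments took the place of a new segmentation. For chromosome ratios, each library was divided by its autosomal median, and 4898 bins with a median ratio over nuclei from 0.25 to 4 were kept. A gain or a loss was a log2 ratio at or beyond 0.2 or -0.2. The multiplier was searched from 1.5 to 6 in steps of 0.05 for the smallest mean squared distance of autosomal ratios to whole numbers. Copies of a chromosome are its median ratio times the multiplier, rounded for counts. A copy number was called whole within 0.2 copies.

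Regions came from the median log2 profile of all nuclei, blind to gate, over all bins of chromosomes 1 to X, by least-squares partitioning with a penalty factor of 5 and at least 5 bins per region. The design did not say how the noise variance is estimated. The median absolute difference of neighbouring bins was 0 in this smooth profile, so 0.5 times the variance of neighbour differences was used, a choice made after seeing the data. Penalty and region borders depend on it. The text names every chromosome with a median beyond 0.2 on the log2 scale in any gate and the 5 with the largest difference in share of altered nuclei. It also names the 15 regions with the largest absolute median and the 5 with the widest spread over nuclei. Chromosomes 1, 5, 15, 16, 18 and Y and the region steps were named after their values were seen.

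The functions were tested on simulated data, with the bins of the table for the multiplier only. With segment noise of 0.05, the multiplier was within 0.1 of the truth in 100% of 150 simulated nuclei that were not doubled and in 56% of 50 doubled ones. The partitioning found 100% of 200 simulated breakpoints within 1 bin, on made-up profiles with independent noise of 0.1 and a known noise variance. The median profile of nuclei was already segmented and its variance was estimated from it. The self-test therefore does not show how exact the regions reported here are. Shares have exact Clopper-Pearson intervals at 95%. By the rule that nuclei of 1 culture are not replicates, no test between gates was run. Alternatives were other thresholds, centring on the mean, all bins, other ranges of the multiplier, chromosome X in the multiplier fit, and leaving out 8 nuclei whose residual from whole copies was above 0.15. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.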

Results

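The data were 96 whole-genome sequencing libraries from KPC1199EGFP, a pancreatic cancer cell line from C57BL/6 mice that carries a green fluorescent reporter, grown as adherent cells and taken at passage 9 without treatment. Nuclei stained with DAPI, a dye that binds DNA, were sorted by DNA content. There were 94 single nuclei, of which 47 came from the 2N gate, 35 from the 2N+ gate and 12 from the 4N gate. The remaining 2 libraries were bulk samples of the 2N and the 2N+ gate. The deposited values are segmented copy ratios in 4906 bins with a median width of 486 kb, so the read depth of each library is unknown. No pair of libraries held identical values. All nuclei came from 1 culture, so each gate is 1 sample of many cells. SDs below describe the spread of nuclei, the exact Clopper-Pearson 95% intervals cover counting error only, and no p-value was computed. Copies are the ratio multiplied by the factor that best brought the autosomal ratios of that nucleus to whole numbers. The copy counts per chromosome and the region steps were chosen after seeing the data.

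The first question was which chromosomes stood above or below the rest in nuclei of the 2N gate. These nuclei did not have a uniform diploid set. Chromosome 4, home of the tumour suppressor gene Cdkn2a, and chromosomes 7, 9, 10 and 13 were at 2 copies in 47 of 47 nuclei. Chromosome 17 was at 3 copies in 46 of 47 nuclei and chromosome 11, which carries Trp53, in 45 of 47. Chromosome 3 was at 3 copies in 42 nuclei and at 4 in 5 nuclei. Chromosome 19 was at 3 copies in 40 nuclei and at 4 in 6 nuclei. Chromosome X was at 1 copy in 43 of 47 nuclei.

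Other chromosomes differed between nuclei of the 2N gate. Chromosome 1 was at 3 copies in 30 nuclei and at 2 in 17 nuclei. Chromosome 18, which carries Smad4, was at 3 copies in 26 nuclei and at 2 in 21 nuclei. Chromosome 2, by its median over bins, was at 2 copies in 18 nuclei, at 3 in 23 nuclei and at 4 in 6 nuclei. Its parts differed: the region from 97908371 to 181748087 was at 2 copies in 2 nuclei, and that from 14885854 to 75743670 in 40 nuclei. The copy numbers of chromosomes 1 to 19 and X formed 24 different sets among the 47 nuclei, and the most frequent set was found in 10 of them. Genes were not placed in bins, because no annotation of the mm9 build was used here.

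**Figure D1:**
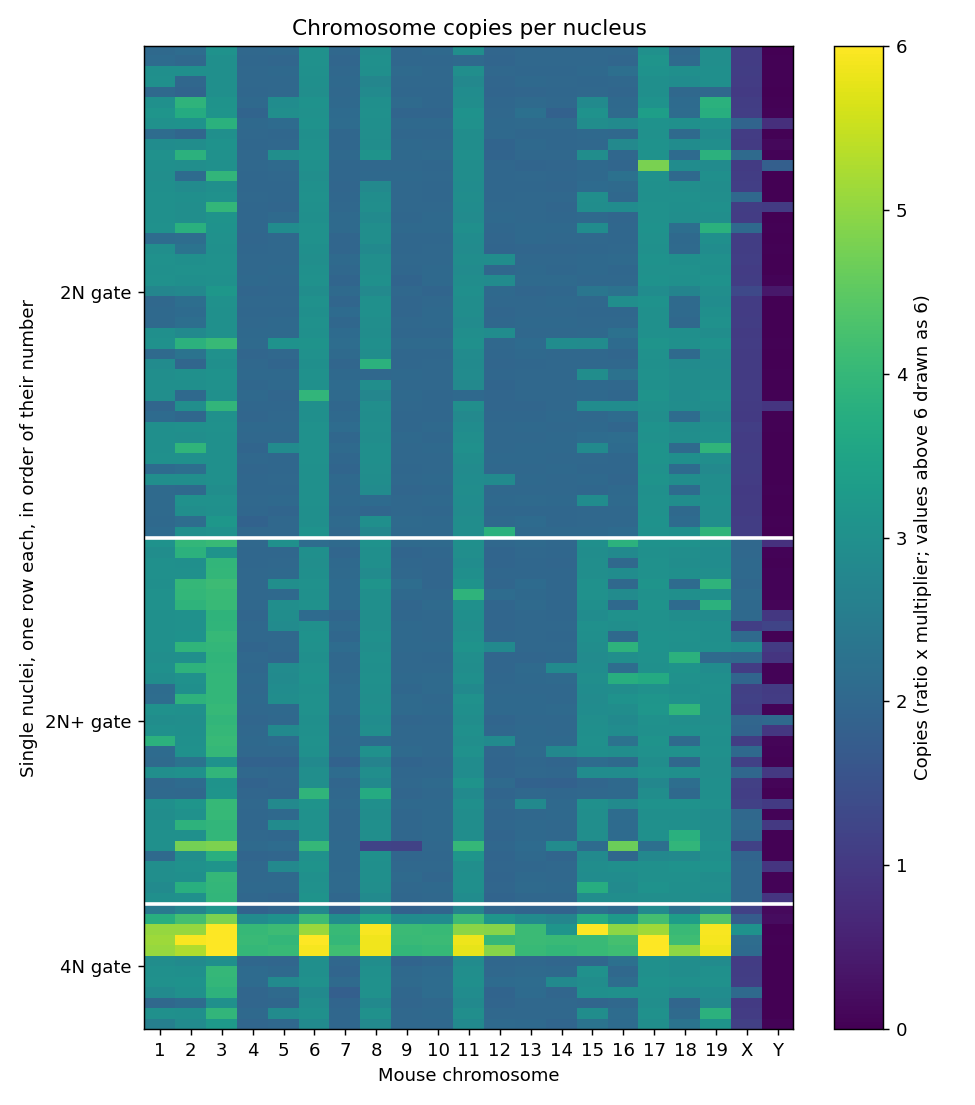
Copies of each mouse chromosome (columns) in each of 94 single nuclei (rows), grouped by sorting gate and ordered by nucleus number; colour gives copies as the ratio times the multiplier of the nucleus, and values above 6 are drawn as 6. Chromosome 3 was at 4 copies or more in 5 of 47 nuclei of the 2N gate and in 30 of 35 nuclei of the 2N+ gate.

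The second comparison asked how nuclei of the 2N+ gate, sorted for more DNA, differed from those of the 2N gate. They more often carried additional copies of chromosomes 3, 15 and X, of chromosome 2, above all outside its distal region, and of chromosome 16, above all its middle. The start of chromosome 8, from 1 to 43640395, was also more often at 3 copies, in 30 of 35 2N+ nuclei and 11 of 47 2N nuclei. Chromosome 3 was at 4 copies or more in 85.7% of 2N+ nuclei (95% interval 69.7 to 95.2, n = 35) and in 10.6% of 2N nuclei (3.55 to 23.1, n = 47). Chromosome 15, which carries Myc, was at 3 copies or more in 88.6% of 2N+ nuclei (73.3 to 96.8) and in 25.5% of 2N nuclei (13.9 to 40.3). Chromosome X was at 2 copies or more in 68.6% of 2N+ nuclei (50.7 to 83.1) and in 8.51% of 2N nuclei (2.37 to 20.4). Chromosome 2, by its median over bins, was at 3 copies or more in 91.4% of 2N+ nuclei (76.9 to 98.2) and in 61.7% of 2N nuclei (46.4 to 75.5). Its distal region, from 97908371 to 181748087, was at 2 copies in only 2 of 47 2N nuclei and 0 of 35 2N+ nuclei. It was at 4 copies or more in 7 and 12 nuclei. The region from 14885854 to 75743670 was at 2 copies in 40 of 47 2N nuclei and 15 of 35 2N+ nuclei. By its median over bins, chromosome 16 was at 3 copies or more in 62.9% of 2N+ nuclei (44.9 to 78.5) and in 10.6% of 2N nuclei (3.55 to 23.1). This difference was largest in the middle of chromosome 16, from 18611456 to 66290027, which had a mean of 2.09 copies in the 2N gate (SD 0.259) and 2.73 in the 2N+ gate (SD 0.644). The regions at both ends had means of 2.68 and 2.56 copies in the 2N gate and 2.97 and 2.82 in the 2N+ gate, and were at 2 copies in 18 and 19 of 47 and in 8 and 9 of 35 nuclei. For each of chromosomes 2, 3, 15, 16 and X, taken by its median over bins, the intervals of both gates were apart.

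For chromosomes 1, 5 and 18 the intervals of both gates overlapped, which does not show that the shares are equal. Chromosome 1 was at 3 copies or more in 28 of 35 and 30 of 47 nuclei, chromosome 5 in 13 of 35 and 6 of 47, and chromosome 18 in 29 of 35 and 26 of 47. Chromosome Y, covered by 3 bins, was at 1 copy or more in 40% of 2N+ nuclei (23.9 to 57.9) and in 8.51% of 2N nuclei (2.37 to 20.4), with intervals apart. Chromosome 4 was at 2 copies in 35 of 35 nuclei of the 2N+ gate as in 47 of 47 of the 2N gate. Inside a nucleus, the ratio of chromosome 3 to chromosome 4, which no multiplier changes, had a median of 1.97 in the 2N+ gate (SD 0.159) and 1.5 in the 2N gate (SD 0.143). The mean number of copies over chromosomes 1 to X had a median of 2.61 in the 2N+ gate (SD 0.125) and 2.39 in the 2N gate (SD 0.120). The 2N+ nuclei had 0 index numbers inside the range of the 2N gate, so no comparison within a batch of indices can be made.

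**Figure D2:**
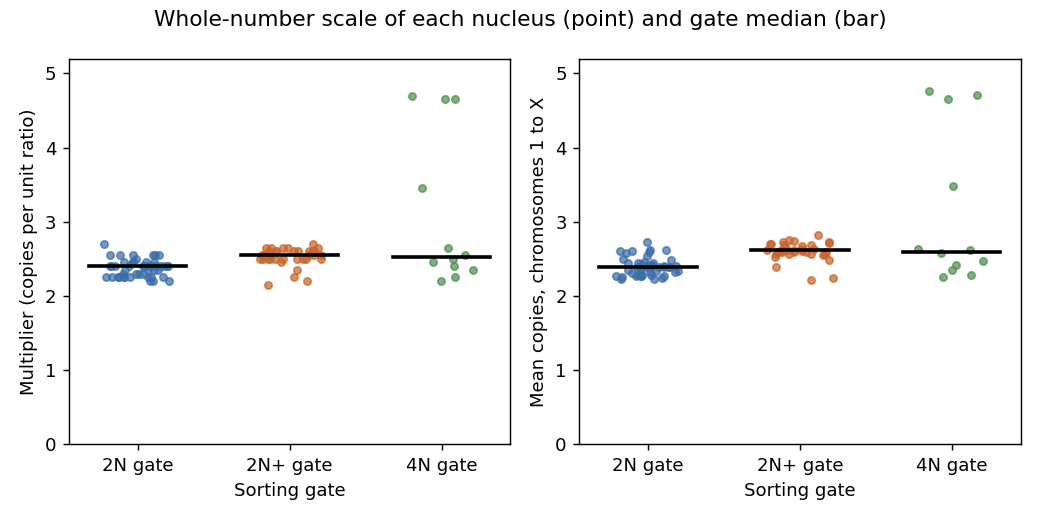
Multiplier (left, copies per unit ratio) and mean copies over chromosomes 1 to X (right) by sorting gate; each point is 1 nucleus and the bar is the median of the gate. The medians of mean copies were 2.39 in the 2N gate and 2.61 in the 2N+ gate, and 3 nuclei of the 4N gate had a multiplier above 4.

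The third comparison asked whether the steps between copy states in the 4N gate had the size seen in the 2N gate, since cells in G2 keep the ratios of G1 cells. The multiplier lay between 2 and 3 in 8 of 12 nuclei of the 4N gate, and in all 47 and 35 nuclei of the 2N and 2N+ gates. Nuclei 3, 4 and 5 of the 4N gate had multipliers of 4.65, 4.65 and 4.70, and nucleus 2 had 3.45. In nucleus 3 chromosome 3 was at 6.98 copies, chromosome 14 at 3.12 and chromosome X at 3.07. The ratio of chromosome 3 to chromosome 4 had a median of 1.66 in the 4N gate (SD 0.180, n = 12). In the self-test on simulated nuclei, the multiplier of doubled genomes was recovered in 100% of cases at a segment noise of 0.02 and in 56% at 0.05, so a doubled genome was not always detectable. With multipliers limited to 2.0 to 3.0, the share of 4N nuclei with 4 or more copies of chromosome 3 went from 66.7% to 33.3%.

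Recurrent regions were taken from the median profile of all 94 nuclei, which was divided into 57 regions. The region farthest from the autosomal median was at the start of chromosome 5 in mm9, from position 1 to 5715257. It covered 5 bins and had a median of 9.03 copies in the 2N gate (SD 1.60), 9.23 in the 2N+ gate (SD 1.73) and 9.31 in the 4N gate (SD 5.18). The neighbouring region of chromosome 5, from 5715258 to 14159645, had medians of 6.09, 6.33 and 7.14 copies. The 4N medians pool 8 of 12 nuclei with multipliers between 2 and 3 and nuclei with larger ones. They are therefore not on the scale of the other gates. As ratios to the autosomal median, the first region was at 4.36 (2N), 3.61 (2N+) and 3.86 (4N). The second was at 2.94, 2.60 and 2.73. The rest of chromosome 5 up to 110993087 was at a median of 2.03 copies in the 2N gate. Both proximal regions were counted as gains in 47 of 47, 35 of 35 and 12 of 12 nuclei, and the lowest value of the first was 2.57 copies in the 4N gate. No library of a normal mouse genome was used here, so the part of this signal that mapping near the chromosome start could add was not measured.

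Of the regions with the widest spread over nuclei, the start of chromosome 1, from 3559438 to 14785728, ranged from 2.07 to 5.87 copies in the 2N gate and was at 5 copies or more in 9 of 47 nuclei. In the 2N+ gate it was at 5 copies or more in 2 of 35 nuclei. The end of chromosome 8 held 3 such regions. From 91050079 to 97123863 the median was 2.52 copies in the 2N gate and 2.50 in the 2N+ gate, between whole numbers. From 97123864 to 117492118 and from 117492119 to 131738871 the medians in the 2N gate were 2.96 and 2.97 copies, and 11 of 47 nuclei had 2 copies in each. Chromosome X was the other region of this kind. The regions with the largest levels besides those on chromosomes 3, 5 and X were parts of chromosomes 2, 6, 11, 17 and 19, which had medians from 2.93 to 3.04 copies in the 2N gate.

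Steps inside chromosomes also differed between gates. The start of chromosome 8, from 1 to 43640395, had fewer copies than the next region in 66% of 2N nuclei (50.7 to 79.1) and in 8.57% of 2N+ nuclei (1.8 to 23.1). In the 4N gate this was seen in 6 of 12 nuclei, with an interval (21.1 to 78.9%) that overlapped the interval of either gate. The middle of chromosome 16 had fewer copies than both its neighbours in 51.1% of 2N nuclei (36.1 to 65.9) and in 11.4% of 2N+ nuclei (3.20 to 26.7), and in 6 of 12 nuclei of the 4N gate. On chromosome 2, the region from 14885854 to 75743670 was lower than both its neighbours in 66% of 2N nuclei, 62.9% of 2N+ nuclei and 58.3% of 4N nuclei, with overlapping intervals. A step of at least 0.5 copies was seen at 622 positions, of which 474 were found in 1 nucleus only and 30 in 5 or more nuclei. Without 6 nuclei that had more than 60 breakpoints, there were 319 positions, of which 232 were found in 1 nucleus only and 28 in 5 or more nuclei. Steps were matched by exact bin, so the same step placed in a nearby bin counts as another position. On chromosome 16, for example, steps at 65773169 and 66290028 were seen in 5 and 28 nuclei. The counts of positions found in 1 nucleus only may therefore be too high.

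**Figure D3:**
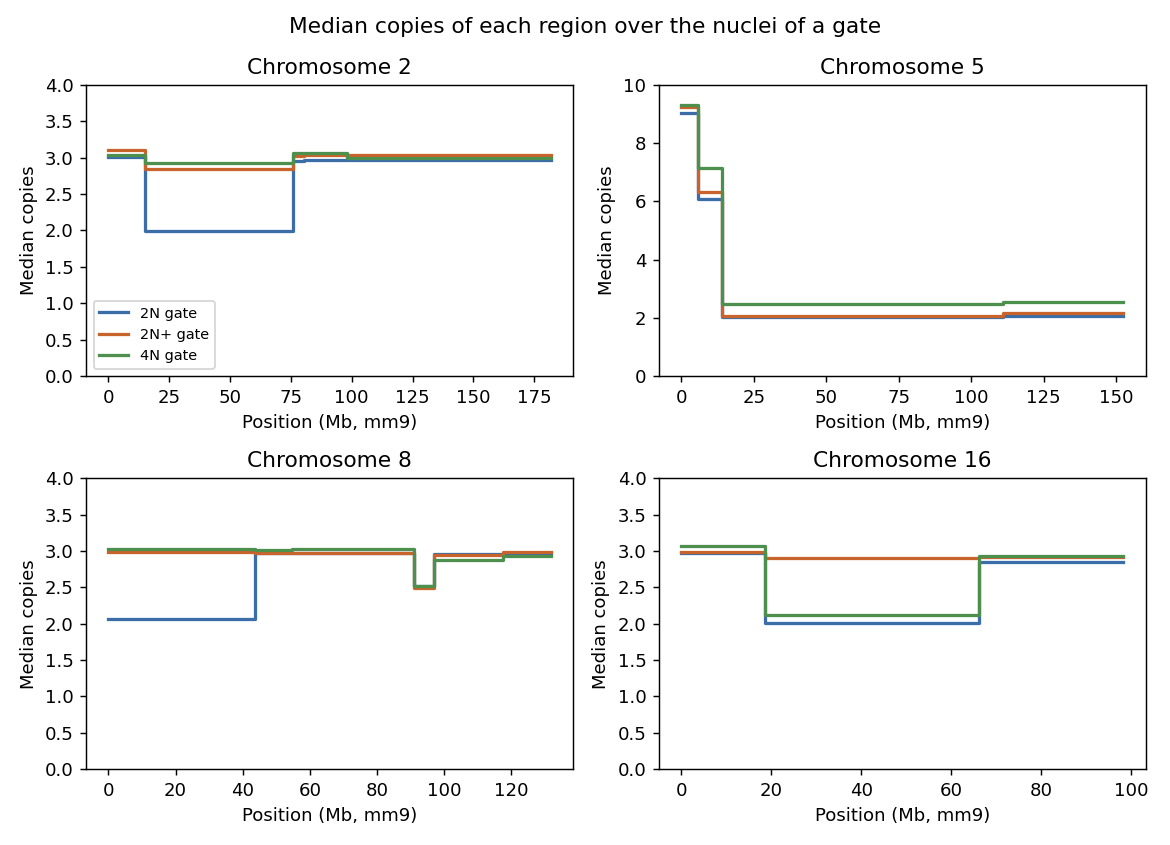
Median copies over the nuclei of a gate (vertical axis) along chromosomes 2, 5, 8 and 16 (horizontal axis, Mb in mm9), with 1 line per sorting gate and 1 step per region. The start of chromosome 5 reached 9.03 copies in the 2N gate, and the start of chromosome 8 was at 2.06 copies in the 2N gate and 2.98 in the 2N+ gate.

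Ratios over the autosomal median of each nucleus, the scale fixed before the data were examined, gave another picture, because this median lay at 2 copies in 35 of 47 nuclei of the 2N gate and in 8 of 35 nuclei of the 2N+ gate. On this scale chromosome 4 had a median log2 ratio of -0.04 in the 2N gate (SD 0.21), -0.52 in the 2N+ gate (SD 0.19) and -0.22 in the 4N gate (SD 0.18), although its copy number was 2 in every nucleus of the first 2 gates. Chromosomes 7, 9, 10, 12, 13 and 14 had medians from -0.04 to -0.03 in the 2N gate and from -0.55 to -0.49 in the 2N+ gate. Chromosomes 6, 8, 11, 17 and 19 had medians from 0.46 to 0.55 in the 2N gate and from 0.03 to 0.06 in the 2N+ gate. Chromosome 3 had medians of 0.55, 0.45 and 0.50 in the 3 gates, chromosome 2 of 0.16, 0.06 and 0.22, and chromosome X of -0.96, -0.54 and -0.97. A gain was called in 29.6% and a loss in 16.1% of chromosomes in the 2N gate, against 17% and 35.1% in the 2N+ gate and 27.9% and 25.4% in the 4N gate. Centred on the mean of autosomal bins instead, losses made up 52.1%, 45.7% and 46.7% of chromosomes in the 3 gates, and gains 33.4% in the 2N gate.

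The number of breakpoints inside chromosomes had a median of 18 in the 2N gate (SD 7.58, range 5 to 34), 20 in the 2N+ gate (SD 19.4, range 8 to 91) and 27 in the 4N gate (SD 31.2, range 10 to 112). Whether these medians differ was not tested. The percent of autosomal bins beyond 0.2 on the log2 scale had medians of 45.8 (SD 8.42), 51.6 (SD 10.4) and 52.3 (SD 12), and shares the dependence on the centre. Centred on the mean of autosomal bins instead, this percent was higher in the 2N gate than in the 4N gate. Profiles of pairs of nuclei had a median Pearson correlation across bins of 0.833 within the 2N gate, 0.820 within the 2N+ gate and 0.753 between both. The SDs over pairs were 0.0828, 0.0919 and 0.0890. Pairs within the 4N gate had a median of 0.814, pairs of 2N and 4N nuclei 0.830, and pairs of 2N+ and 4N nuclei 0.787. Bins are not independent replicates.

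The last comparison set the 2 bulk libraries, which have no replicate, against the single nuclei of their gate. Chromosome 3 had a ratio of 1.33 in the 2N bulk library and a mean of 1.32 ± 0.111 (SD, n = 47) over 2N nuclei. In the 2N+ bulk library it was 1.5, against 1.53 ± 0.110 (SD, n = 35) over 2N+ nuclei. Chromosome X was at 0.50 and 0.674 in the 2 bulk libraries, against means of 0.485 ± 0.101 and 0.696 ± 0.174 over nuclei. Chromosome Y was at 0.0592 and 0.190, against means of 0.0536 and 0.180. The bulk profile correlated across bins at 0.987 (2N) and 0.994 (2N+) with the mean of its own gate and at 0.907 and 0.924 with the mean of the other gate. Over chromosomes 1 to X, the largest difference from the mean of nuclei was 0.0720 in ratio, on chromosome 8 of the 2N gate (1.14 in the bulk library and a mean of 1.21 over nuclei). With 1 bulk library per gate and nuclei of 1 culture, these differences have no error to be judged by.

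**Figure D4:**
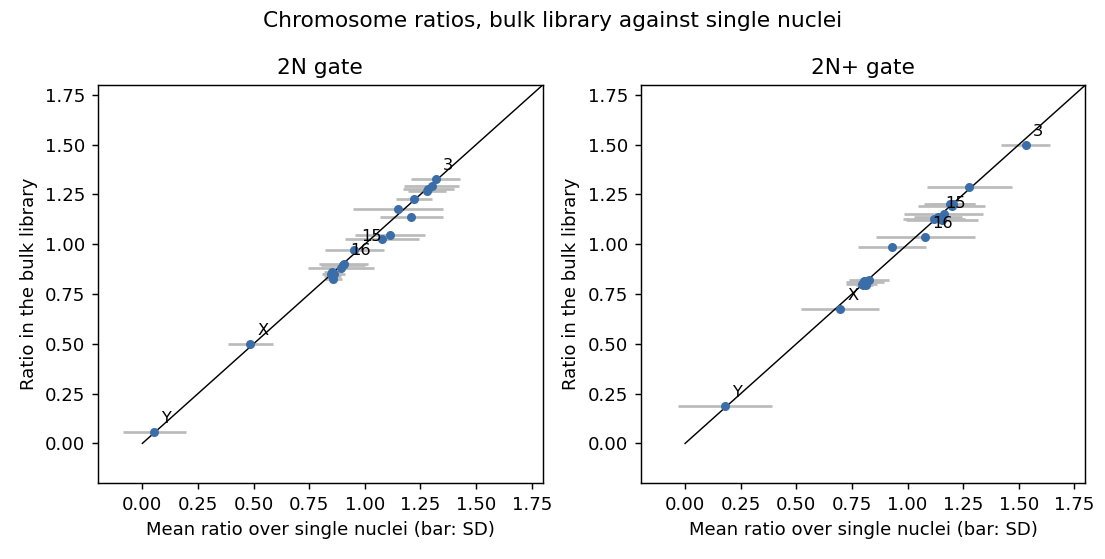
Ratio of each chromosome in the bulk library (vertical axis) against its mean over single nuclei of the same gate (horizontal axis, bars are SDs over nuclei), for the 2N gate (left) and the 2N+ gate (right); the line marks equal values. Chromosome 3 was at 1.33 and 1.5 in the bulk libraries and at means of 1.32 and 1.53 over nuclei.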

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

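The alternatives that leave out nuclei of high residual or of many breakpoints, limit multipliers to 2.0 to 3.0, add chromosome X to the multiplier fit, count only steps of 0.5 copies, change the penalty, or centre the percent of altered bins on the mean were chosen after seeing the data. Of 618 alternative values for 207 results, 565 moved by less than the spread of nuclei, the counting interval or 1.5 times, and none changed sign where it had been called. The shares of 2N and 2N+ nuclei with additional copies of chromosomes 2, 3, 15, 16 and X stayed within their intervals under the alternatives run on them. Without the 8 nuclei of high residual, the shares for chromosome 3 were 11.1% (2N) and 87.5% (2N+). Centring on the mean of autosomal bins moved the most. It raised the chromosomes beyond 0.2 in the 2N gate from 7 to 18, the gains there from 29.6% to 33.4%, and the losses in the 2N, 2N+ and 4N gates to 52.1%, 45.7% and 46.7%. It also raised the altered autosomal bins to 92.8% (2N) and 75.2% (4N), and the regions beyond 0.2 in the 2N gate from 28 to 52. A threshold of 0.3 lowered 4N losses to 15.4%, altered bins to 36.5% and regions from 35 to 20. Multipliers limited to 2.0 to 3.0 lowered the 4N shares for chromosomes 3, X and 16 to 33.3%, 8.33% and 8.33%, by construction for the nuclei with larger multipliers. Steps of 0.5 copies or more lowered the median breakpoints of the 2N gate from 18 to 9. For the other moves the cause was not tested. Thinning, minimum totals, GC correction, merged bins, the bin noise limit and a higher penalty per nucleus were not run, since ratios carry no depth. No paired analysis was possible because the numbers only name nuclei and no test was fitted.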

Other observations

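Some chromosome states came together in the same nuclei. These combinations were chosen after seeing the data and are given as counts. Chromosomes 3, 15 and X were at 3, 2 and 1 copies in 34 of 47 nuclei of the 2N gate and in 3 of 35 of the 2N+ gate. They were at 4, 3 and 2 copies in 1 nucleus of the 2N gate and in 20 of the 2N+ gate. A further set, with chromosome 19 at 4 copies, 18 at 2, 5 at 3 and 15 at 3, was found in 5 nuclei of the 2N gate, 2 of the 2N+ gate and 1 of the 4N gate. Of the 18 nuclei with chromosome Y, 16 had chromosome 3 at 4 copies, namely 13 of 14 in the 2N+ gate and 3 of 4 in the 2N gate. Among all nuclei of these gates, chromosome 3 was at 4 copies or more in 30 of 35 and in 5 of 47. In the 2N+ gate, the share with chromosome 3 at 4 copies among nuclei with chromosome Y is thus near that of the whole gate. In the 2N gate it was higher than in the whole gate, but on only 4 nuclei with chromosome Y. Over all 94 nuclei there were 57 sets of copy numbers of chromosomes 1 to X, of which 9 were found in 2 or more nuclei and 4 in more than 1 gate. In the gene order of GRCm38.p6, Cdk6, which drives entry into the cell cycle and was on the oncogene list fixed beforehand, is number 25 of 1269 protein-coding genes from the start of chromosome 5. Whether it lies in the bins of high ratio there was not determined, and the part that mapping could add to their ratio was not measured.

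The tests below on replicated DNA, the multiplier, the index batch and the bulk distance were chosen after their values were seen, the unrounded correlation was added after the rounded result, and the rule for weighing both correlations was changed after their values were seen. The first pattern is the additional copies of chromosomes 3, 15 and X in the 2N+ gate. Partly replicated DNA of 2N karyotypes could leave chromosome X between whole copies, and 100% of 2N+ nuclei had it within 0.2 of a whole copy. This value is a median over the chromosome, which can lie near a whole copy even when only part of its bins is replicated. That value alone cannot exclude partly replicated DNA. Replication should also raise other chromosomes and add steps inside them. Chromosomes 4, 7 and 10 were within 0.2 of 2 copies in 35 of 35 2N+ nuclei. Steps of 0.5 copies or more had a median of 10 in the 2N+ gate (range 3 to 73) and 9 in the 2N gate (4 to 25). For nuclei without many breakpoints, these values argue against replication as the source of whole additional copies. Replication of part of a chromosome is not excluded. A wrong multiplier would leave the ratio of chromosome 3 to 4 unchanged, but its median was 0.466 higher than in the 2N gate, beyond the SDs of 0.143 and 0.159. The index numbers of the 2N and 2N+ gates do not overlap, but a shift of ratios shared by the libraries of an index range would not leave chromosome X within 0.2 of 1 copy in 11 of the 2N+ nuclei and of 2 copies in 23, nor give chromosome 3 at 4 copies with 15 at 3 in 4 nuclei of the 2N gate. It stays a hypothesis, found and tested on the same nuclei, that the sort by DNA content may have drawn on a subpopulation with more chromosomes.

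The second pattern is 6 nuclei with over 60 breakpoints, namely nuclei 22, 24 and 31 of the 2N+ gate and 7, 9 and 10 of the 4N gate. Random amplification noise would leave their deviations unrelated, and a shared pattern, such as replication timing or GC content, would relate them. Residuals from whole copies had a median correlation of 0.0448 over 15 pairs, below the 0.181 of pairs of other nuclei, but rounding removes deviations above 0.5 copies. Without rounding, ratios over the chromosome median gave 0.304 (0.0317 to 0.666), against 0.231 for pairs of other nuclei, a comparison that the bounds set beforehand had left out. Pairs among 2N+ nuclei 22 and 24 and 4N nucleus 10 were at 0.666, 0.554 and 0.469. The pair of 4N nuclei 7 and 9 was at 0.485, and the other pairs were from 0.0317 to 0.362. Nuclei 22, 24 and 10 all had the set of copy numbers most frequent in the 2N gate. Whether that adds to their correlation was not tested. Over all pairs the measures point opposite ways, so noise and a shared pattern cannot be told apart for the 6 nuclei as a set.

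The third pattern is 6 nuclei of the 4N gate, of which 3, 4 and 5 had a multiplier above 4 and 1, 2 and 12 a residual from whole copies above 0.15. For 2 of nuclei 3, 4 and 5, the best average of a pair of 2N nuclei came closer than the best single one by more than usual, with ratios of pair to single error of 0.688 (nucleus 4) and 0.333 (nucleus 5), below the 5th percentile of 0.744 for 2N nuclei. Nuclei 2 and 3, at 0.806 and 0.908, were above it, while nuclei 1 and 12, at 0.686 and 0.706, were below it too. All 3 of nuclei 1, 2 and 12 were closer to the 2N bulk library, at 0.0453, 0.0670 and 0.0536, than each of 45 nuclei of the 2N gate with a low residual, the nearest of which was at 0.0748, but so were nuclei 4 and 5, at 0.0696 and 0.0671, so this distance does not separate DNA of many nuclei from that of a pair. Libraries holding DNA of more than 1 nucleus may be candidate sources for these nuclei other than nucleus 3. For nucleus 3 they are not excluded, because only pairs of 2N gate nuclei were tried and no pair with a 2N+ nucleus. A tetraploid cell formed by fusion of a pair of cells would give the same average as a pair. A doubled genome with later changes would also have smaller steps. Neither was tested apart. A residual above 0.15 was not particular to the 4N gate, since 2 nuclei of the 2N gate and 3 of the 2N+ gate had it too. Nucleus 24 of the 2N gate had chromosomes 1 and X between whole numbers, at 2.75 and 1.33 copies. Its distance to the 2N bulk library was 0.0774, above the 0.0748 of the nearest nucleus with a low residual. Whether it holds DNA of more than 1 nucleus was not tested.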
